A study of Mus musculus with 12 samples.

How the data were processed

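RNA from microdissected mouse kidney structures was extracted with TRIzol, amplified in 2 rounds with T7 polymerase, labelled with biotin and hybridized to MG_U74Av2 arrays, per the labels. The deposited table holds 1 column of intensity values per array, on a linear scale and with negative values, for 12422 probe sets besides 66 controls. GCOS is the tool named in the submitters' processing notes, with no version; the summary method, background correction and scaling are not given in the sources used here. Between 19.5% and 25.0% of the deposited values per array were at or below 0, and the array medians differed by a factor of up to 17.8, so the arrays had not been brought to a common scale. The arrays fell into 4 groups of 3: renal vesicle (replicates 2, 3 and 4) and pooled S-shaped body (1, 2 and 3), each from pools of 20 structures, collecting duct (1, 2 and 3) and single S-shaped body (3, 4 and 5), each from 1 unpooled sample. No array was left out, and 0 pairs of arrays were identical.

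Because the medians differed by more than a factor of 2, the 12 arrays were quantile normalized without the controls, as planned for that case. Values under 0 were set to 0, a pseudocount of 7.22 (25% of the median of all values) was added, and log2 was taken. Probe sets with a mean under the 25th percentile of the arrays in a fit were left out, which left 9316 tested. A probe set counted as above background on an array when its deposited signal exceeded the distance by which the lowest 5% of values lie below 0. Where a gene was at or under that level on every array of the dimmer group, a bound on the fold against that level is given in place of the fitted fold, with the adjusted p of the fit. Probe sets were matched to genes with the annotation supplied for the array: 10833 had 1 symbol, 396 several and 1193 no symbol, giving 8251 genes. Statements on genes use, per gene, the probe set with 1 symbol and the highest mean.

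Differences were tested with limma 3.58.1 in R 4.3.3 (linear model per probe set, empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. Renal vesicles, pooled S-shaped bodies and collecting duct were fitted together on 9 arrays. Single against pooled S-shaped bodies, single S-shaped bodies against collecting duct, and pooled S-shaped bodies against collecting duct were also fitted on 6 arrays each. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over all lists and comparisons of a fit, and again with an estimated correlation; a list needed 3 measured members. The 21 lists cover nephron progenitors, early nephron, podocyte precursors, proximal tubule, distal tubule and loop of Henle, ureteric bud and collecting duct, epithelial junctions and polarity, basement membrane, stroma and interstitium, endothelium, red blood cells, macrophages and leukocytes, neurons and glia, cell cycle, Notch pathway, Wnt pathway, immediate early and heat shock response, oxidative phosphorylation, glycolysis, the 3 genes that the series text names, and cytosolic ribosomal proteins. Some genes stand in more than 1 list. The groups, tests, lists, settings to vary and naming rule were fixed before the data were examined; the floor at 0, the background level and a pseudocount of 50 were chosen after seeing the data.

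Genes were named by rule: the 5 called genes per direction with the largest change whose groups do not overlap and whose higher mean exceeds the median of tested probe sets; the 2 called members of each list with the largest change; and Wt1, Wnt4, Pax8, Lhx1, Jag1, Six2, Ret, Calb1, Gata3, Wnt11 and Hnf4a where measured. Jag1 had no probe set with its symbol, and Ret and Hnf4a fell under the filter, at the 3.72 and 8.26 percentile of mean signal. Only a part of the genes that this rule selects is printed below. Alternatives were a pseudocount equal to the median, 10% of the median, or 50; the deposited scale; scaling to the 75th percentile of each array; no filter and a filter at the 50th percentile; empirical Bayes without the trend; array weights; all 12 arrays in a fit; only the groups compared; a 2-fold threshold; the replicate number as a block; the mean over a gene's probe sets in list tests; and leaving out each array in turn. Single and pooled arrays were compared by exact permutation of per-array values. Chance overlap of calls under shared controls was simulated 20 times. The fit was tested on simulated data of 9316 probe sets, of which 67, 67 and 66 were changed by 1, 2 and 3 log2 units. For pooled S-shaped bodies against renal vesicles it recovered 56.7%, 89.6% and 100% of these, with 7 false calls. For single against pooled it recovered 41.8%, 80.6% and 92.4%, with 12 false calls. The false calls are to be set against the calls made, not against all probe sets. Intervals of list medians come from 10000 bootstrap resamples over genes, and so measure the spread between the genes of a list, not between samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.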

Results

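Gene expression was measured on 12 Affymetrix MG_U74Av2 arrays of structures dissected from kidneys of Swiss Webster mouse embryos at E14.5. There were 4 groups of 3 arrays. Renal vesicles, the earliest epithelial stage of the nephron, and S-shaped bodies, a later stage in which the glomerular and tubular parts take shape, were each collected in pools of 20 structures. Single S-shaped bodies were also amplified without pooling, and unpooled collecting duct, which derives from the ureteric bud, is the reference of the study. The comparisons address which genes set the early nephron structures apart from the collecting duct, how the pooled nephron stages differ, and how RNA amplified from 1 structure compares with RNA from a pool. The labels name the samples biological replicates and do not say which came from separate embryos, so the p-values measure only the spread between these samples.

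Mean deposited intensity per array was 116 ± 13.0 in renal vesicles, 226 ± 19.4 in pooled S-shaped bodies, 304 ± 51.0 in collecting duct and 47.0 ± 24.6 in single S-shaped bodies (SD, n = 3 arrays each). The share of probe sets above background was 58.3%, 56.7%, 56.1% and 51.7% in the same order. After quantile normalization, arrays of a group correlated across probe sets with r between 0.95 and 0.96 in renal vesicles, 0.97 and 0.97 in pooled S-shaped bodies, 0.97 and 0.98 in collecting duct, and 0.91 and 0.94 in single S-shaped bodies. Probe sets are not independent replicates. The ratio of the 3′ to the middle beta-actin control probe set was 3.67 ± 0.385 in pooled S-shaped bodies, against 8.58 ± 0.611 in renal vesicles, 8.25 ± 2.09 in collecting duct and 8.69 ± 1.50 in single S-shaped bodies (SD, n = 3 each). The 3′ to 5′ ratio of beta-actin was highest in single S-shaped bodies, at 85.7 ± 8.64, with 39.6 ± 3.61 in renal vesicles, 38.3 ± 7.65 in pooled S-shaped bodies and 51.2 ± 33.4 in collecting duct. That of the Gapdh controls was 23.9 ± 3.82 in pooled S-shaped bodies and 10.96 ± 3.23, 10.3 ± 1.55 and 10.8 ± 2.00 in renal vesicles, collecting duct and single S-shaped bodies. The number of arrays per group limits the precision of each value.

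Renal vesicles were compared with collecting duct to find the genes of the newly formed nephron epithelium. In renal vesicles 8 of 11 nephron progenitor and 11 of 14 early nephron genes were higher, and 17 of 23 ureteric bud and 20 of 23 junction genes were lower. These lists were called at the preset correlation between genes and not with an estimated correlation (adjusted p = 0.0743 for each). Wt1, a regulator of nephron and podocyte formation, averaged 8.81 ± 1.06 in renal vesicles and 4.78 ± 0.13 in collecting duct on the log2 scale (SD, n = 3 each), a log2 change of 4.03 ± 0.41 (SE, adjusted p = 4.42e-05). Pax8, a paired box factor of the early nephron, averaged 8.32 ± 0.11 and 5.37 ± 0.20 (log2 change 2.95 ± 0.28, adjusted p = 2.33e-05). Lhx1, a LIM homeobox factor needed in the renal vesicle, was above background on the 3 renal vesicle arrays and on 0 of the 3 collecting duct arrays, a difference of at least 5.59-fold, adjusted p = 1.86e-06. Wnt4, the signal that drives mesenchyme into epithelium, was higher by less (log2 change 1.49 ± 0.27, adjusted p = 0.00255). Krt19, a keratin of simple epithelia, averaged 11.31 ± 0.18 in collecting duct and stayed under background in renal vesicles, at least 109-fold, adjusted p = 4.28e-08.

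Of 11 measured nephron progenitor genes, 8 were higher, 0 lower and 3 did not pass (8 and 0 adjusted over the list alone). Their median log2 change was 2.71, or 2.05 with 6 members at their bound (camera adjusted p = 9.14e-07, or 0.0743 with an estimated correlation). Uncx, a homeobox gene, and Hoxa11, a Hox gene of the metanephric mesenchyme, were under background in collecting duct and at least 21.9-fold and 10.3-fold higher in renal vesicles (adjusted p = 4.55e-07 and 3.40e-07). Six2, which maintains the progenitors, was also higher (log2 change 2.05 ± 0.20, adjusted p = 3.59e-05). Among 14 early nephron genes, 11 were higher, 0 lower and 3 did not pass (11 and 0 adjusted over the list alone), with a median of 2.77, or 2.03 with 4 members at their bound (camera adjusted p = 3.33e-07, or 0.0743 with an estimated correlation). Of the 14, 8 also stand in another list. Hey1, a Notch target, changed by 5.88 ± 0.32 on the log2 scale (adjusted p = 4.76e-07; above background on 1 of 3 collecting duct arrays), and the Notch ligand Dll1 by at least 6.27-fold, adjusted p = 5.95e-07. The genes that the series text names, Wt1, Wnt4 and Pax8, had 3 of 3 higher (camera adjusted p = 0.00117, or 0.0999 with an estimated correlation). The text names them for these structures, so they are not independent evidence of direction. Podocyte genes had 7 higher and 1 lower of 13 (7 and 1 adjusted over the list alone), with a median of 1.15, or 0.94 with 3 members at their bound (camera adjusted p = 0.00146, or 0.343 with an estimated correlation). Foxc2, a forkhead factor of podocyte precursors, was at least 54.0-fold, adjusted p = 3.22e-08, and Ptpro, a podocyte phosphatase, at least 18.3-fold, adjusted p = 0.000765. Ptpro differed widely between the renal vesicle arrays, at 6.79, 10.95 and 8.94 in replicates 2, 3 and 4, and the mean over the podocyte genes was 7.03, 8.60 and 7.69.

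Ureteric bud and collecting duct genes were lower in renal vesicles for 17 of 23 members and higher for 1 (17 and 1 adjusted over the list alone), with a median log2 change of -2.66 (camera adjusted p = 1.44e-11, or 0.0743 with an estimated correlation). Gata3, a transcription factor of the ureteric bud, changed by -3.29 ± 0.35 (adjusted p = 5.77e-05). Krt8, the partner keratin of Krt18, changed by -6.82 ± 0.85 (adjusted p = 0.000194; above background on 1 of 3 renal vesicle arrays). Outside the list, Foxa1, a forkhead factor, changed by -6.64 ± 0.49 (adjusted p = 3.64e-06, above background on 1 of 3 renal vesicle arrays). Oit1, also not a member, was lower by at least 29.4-fold, adjusted p = 7.33e-08. Wnt11, a ureteric tip signal, was above background on 2 of 3 renal vesicle arrays and 0 of 3 collecting duct arrays, at least 1.76-fold, adjusted p = 0.0169, with an adjusted p of 0.00525 to 0.0747 over the alternatives. Calb1, a calcium-binding protein of the ureteric bud, was above background on 1 of 3 renal vesicle arrays and 0 of 3 collecting duct arrays (adjusted p = 0.302). In renal vesicles replicate 3 was highest for Calb1 (8.72, with 2.85 and 3.47 in replicates 2 and 4), Krt8 (6.47, with 2.85 and 3.41), Krt7 (7.51, with 2.85 and 4.22) and Wnt11 (7.10, with 4.96 and 4.49). The mean over the ureteric bud and collecting duct genes was 5.43 in replicate 3, with 4.43 and 4.49 in replicates 2 and 4 and 7.60 to 7.71 in collecting duct. Of 23 genes of epithelial junctions and polarity, 0 were higher, 20 lower and 3 did not pass (0 and 22 adjusted over the list alone), with a median of -1.58 (camera adjusted p = 1.37e-13, or 0.0743 with an estimated correlation). Cldn4, a claudin of the collecting duct, was lower by at least 42.5-fold, adjusted p = 2.21e-07. Genes of proximal tubule (2 higher and 2 lower of 12, camera adjusted p = 0.881) and of distal tubule and loop of Henle (1 higher and 1 lower of 9, camera adjusted p = 0.730) did not move as lists. On the deposited scale both were called (0.0405 and 0.0313; up to 0.992 and 0.960 over the alternatives). The largest called proximal tubule members were Gatm, of creatine synthesis (log2 change 1.80 ± 0.24, adjusted p = 0.000357), and Ass1, of the urea cycle (log2 change -1.60 ± 0.30, adjusted p = 0.00308). Ass1 was above background on 1 of 3 renal vesicle arrays. Those of distal tubule and loop of Henle were Irx3, an Iroquois factor (log2 change 2.78 ± 0.32, adjusted p = 0.000110), and Wfdc2 (log2 change -2.19 ± 0.28, adjusted p = 0.000262).

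Markers of other cell types also differed. Endothelial genes were higher for 6 of 15 members and lower for 1 (8 and 1 adjusted over the list alone), with a median of 1.06, or 0.17 with 10 members at their bound (camera adjusted p = 0.000570, or 0.216 with an estimated correlation). Of these genes, 6 were above background on the 3 renal vesicle arrays and 1 on the 3 collecting duct arrays. Cldn5, the tight junction claudin of vessels, was higher in renal vesicles by at least 46.0-fold, adjusted p = 2.78e-07. Eng, an endothelial coreceptor, was higher by 4.44 ± 0.60 on the log2 scale (adjusted p = 0.000350, above background on 1 of 3 collecting duct arrays). Stroma genes were higher for 12 of 24 and lower for 1 (13 and 1 adjusted over the list alone; median 0.93, or 0.42 with 13 members at their bound; camera adjusted p = 0.000177, or 0.250 with an estimated correlation). Cxcl12, a stromal chemokine, was at least 14.0-fold, adjusted p = 4.42e-06, and Meis1 at least 2.88-fold, adjusted p = 5.21e-06. The stroma call was lost with a filter at the 50th percentile, and its adjusted p was 1.49e-09 to 0.0997 over the alternatives. Basement membrane genes had 7 higher and 3 lower of 15 (8 and 4 adjusted over the list alone; median 0.51; camera adjusted p = 0.0129, or 0.222 with an estimated correlation). Without renal vesicle replicate 3 its camera adjusted p was 0.0717, and with the mean of a gene's probe sets 0.0567 (5.10e-06 to 0.0717 over the alternatives). Nid2, a nidogen, was at least 20.2-fold, adjusted p = 7.33e-08. Lama4, a laminin chain, was at least 36.1-fold, adjusted p = 3.22e-08, while its other probe set had the opposite sign and did not pass (adjusted p = 0.472). Red blood cell genes (1 higher and 2 lower of 9, camera adjusted p = 0.839), macrophage and leukocyte genes (0 higher and 3 lower of 6, 0.223) and genes of neurons and glia (0 higher and 0 lower of 8, 0.737) did not move as lists.

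Of 24 cell cycle genes, 15 were higher, 1 lower and 8 did not pass (16 and 1 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 8.09e-06, or 0.123 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose (log2 change 1.74 ± 0.18, adjusted p = 5.77e-05). On the deposited scale the list was not called (camera adjusted p = 0.112; 3.72e-07 to 0.112 over the alternatives). Wnt pathway genes had 10 higher and 1 lower of 21 (10 and 2 adjusted over the list alone; median 0.64, or 0.54 with 5 members at their bound; camera adjusted p = 0.00351, or 0.0999 with an estimated correlation). Higher members included Sfrp2, a secreted Wnt modulator (log2 change 3.44 ± 0.17, adjusted p = 2.78e-07), and Ccnd1, cyclin D1 (log2 change 3.26 ± 0.29, adjusted p = 1.51e-05). Notch pathway genes had 5 higher and 2 lower of 15 (6 and 3 adjusted over the list alone; camera adjusted p = 0.204). They were called on the deposited scale (0.00700) and with the replicate number as a block (0.0421), with 0.00700 to 0.876 over the alternatives. Immediate early and heat shock genes were higher in collecting duct, with 15 of 22 members lower in renal vesicles and 1 higher (15 and 2 adjusted over the list alone; median -2.04; camera adjusted p = 6.71e-07, or 0.107 with an estimated correlation). Atf3, a stress-induced transcription factor, averaged 9.93 ± 0.46 in collecting duct and 5.57 ± 0.37 in renal vesicles (log2 change -4.36 ± 0.26, adjusted p = 9.43e-07). Klf6 changed by -4.21 ± 0.44 (adjusted p = 5.42e-05). The collecting duct samples were not pooled, whereas the renal vesicles were. Glycolysis genes had 0 higher and 2 lower of 14 (0 and 2 adjusted over the list alone; median -0.36; camera adjusted p = 0.0456, or 0.343 with an estimated correlation). That list was not called without renal vesicle replicate 4 (0.0954), collecting duct replicate 1 (0.126) or collecting duct replicate 3 (0.0718), with adjusted p of 0.00863 to 0.212 over the alternatives. Oxidative phosphorylation (2 higher and 1 lower of 28, camera adjusted p = 0.359) and cytosolic ribosomal protein genes (3 higher and 0 lower of 28, 0.737) were not called as lists. With scaling to the 75th percentile the ribosomal list was called (0.0273; 0.0273 to 0.998 over the alternatives).

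limma called 2225 of 9316 probe sets between renal vesicles and collecting duct, 1144 higher and 1081 lower in renal vesicles, of which 1323 changed at least 2-fold. These calls cover 1726 of 6746 genes. In 3682 probe sets (39.5%) the arrays of the groups did not overlap, where chance gives 10%.

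**Figure D1:**
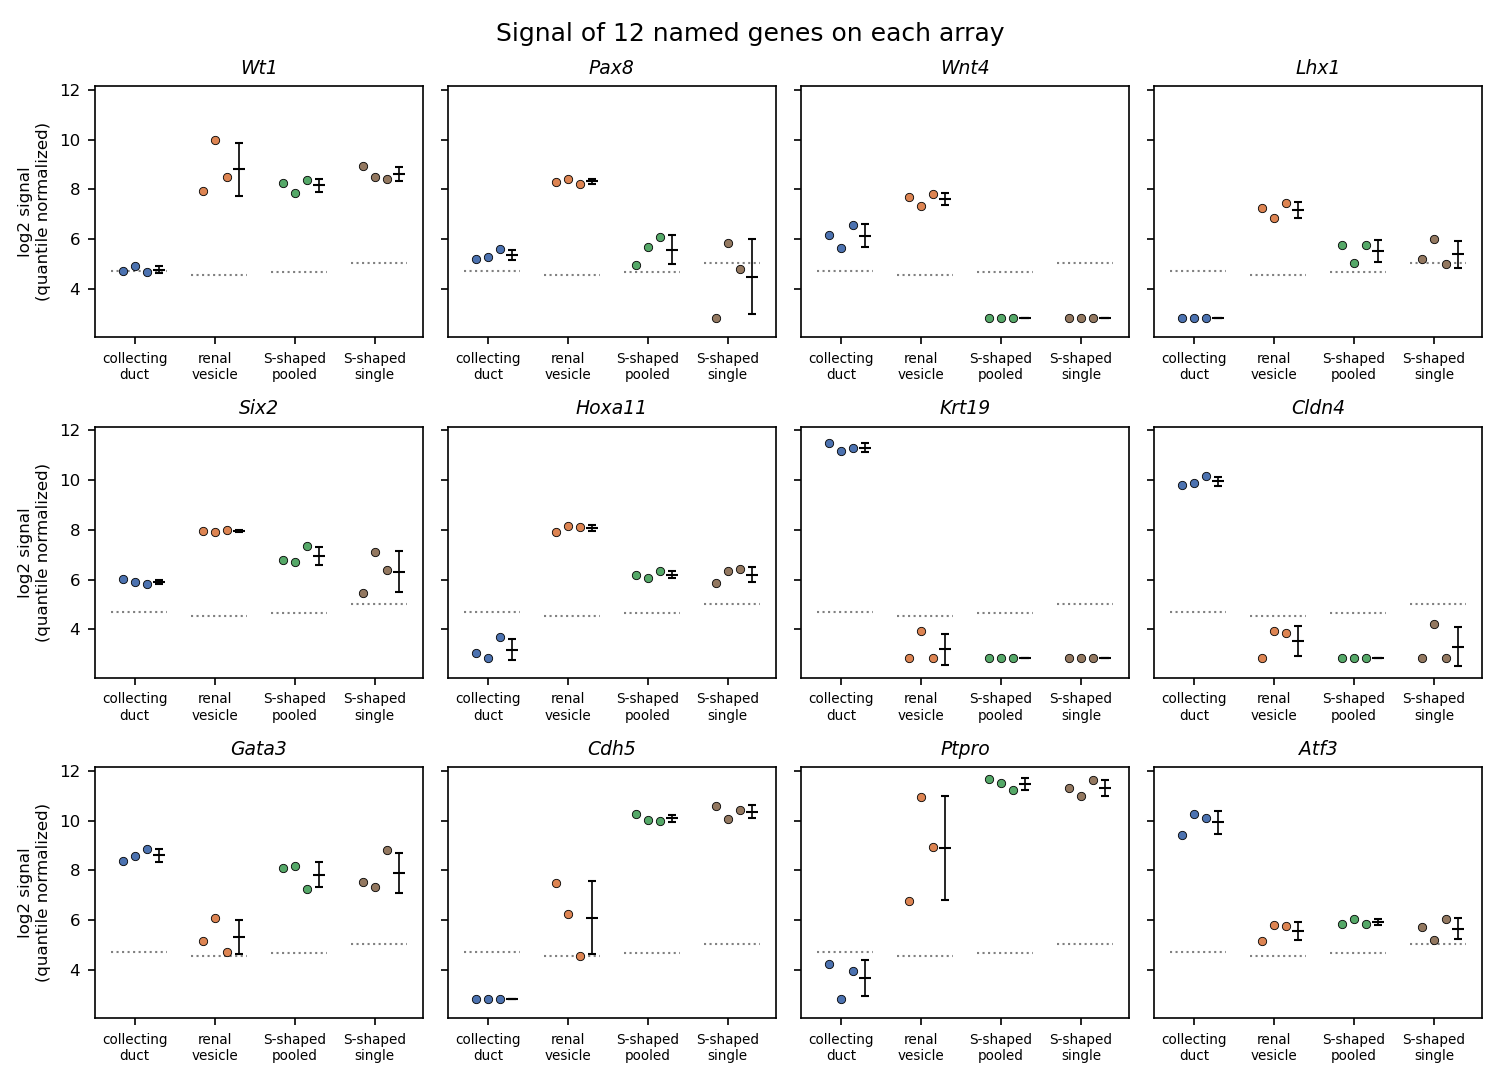
Log2 signal after quantile normalization (vertical axis) of 12 named genes on the 12 arrays, by group; points are arrays, bars the mean ± SD of 3 arrays, and the dotted line the mean background level of the group. Wt1 averaged 8.81 in renal vesicles and 8.17 in pooled S-shaped bodies against 4.78 in collecting duct, while Krt19 averaged 11.31 in collecting duct and 3.21 in renal vesicles.

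Pooled S-shaped bodies were compared with the same collecting duct arrays to find the genes of the later nephron structure. In S-shaped bodies 10 of 13 podocyte and 15 of 15 endothelial genes were higher, and 16 of 23 ureteric bud and 21 of 23 junction genes were lower. The calls of these lists at the preset correlation were lost with an estimated correlation (adjusted p = 0.198, 0.0743, 0.0999 and 0.0743). Ptpro averaged 11.47 ± 0.23 in S-shaped bodies (log2, SD, n = 3) and was under background in collecting duct, at least 109-fold, adjusted p = 2.27e-05. Wt1 was higher (log2 change 3.40 ± 0.41, adjusted p = 8.12e-05). Pax8 did not pass the test (log2 change 0.21 ± 0.28, adjusted p = 0.597). Wnt4 was under background on the 3 S-shaped body arrays and lower than in collecting duct by at least 2.77-fold, adjusted p = 5.64e-06. Cdh5, the cadherin of endothelial junctions, averaged 10.09 ± 0.15 and was at least 41.9-fold, adjusted p = 2.79e-06. Krt19 was lower by at least 100.3-fold, adjusted p = 2.60e-08.

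Of 13 podocyte genes, 10 were higher, 0 lower and 3 did not pass (12 and 0 adjusted over the list alone), with a median log2 change of 3.19 (camera adjusted p = 9.14e-07, or 0.198 with an estimated correlation). Foxc2 was at least 67.4-fold, adjusted p = 2.60e-08. Nephron progenitor genes had 7 higher and 1 lower of 11 (7 and 1 adjusted over the list alone; median 1.15, or 1.05 with 4 members at their bound; camera adjusted p = 0.00695, or 0.158 with an estimated correlation). Hoxa11 was at least 2.83-fold, adjusted p = 6.50e-06, Ncam1, a cell adhesion molecule, changed by 2.43 ± 0.22 (adjusted p = 1.09e-05), and Six2 by 1.05 ± 0.20 (adjusted p = 0.00196). Early nephron genes had 5 higher and 2 lower of 14 (5 and 2 adjusted over the list alone; median 0.19) and were not called as a list (camera adjusted p = 0.123; 0.0288 to 0.184 over the alternatives, the lowest on the deposited scale). Cdh4, a cadherin, was at least 16.7-fold, adjusted p = 6.90e-08, Hey1 changed by 4.52 ± 0.32 (adjusted p = 1.86e-06), and Lhx1 was at least 1.77-fold, adjusted p = 3.28e-05. The series-named genes had 1 of 3 higher and 1 lower (camera adjusted p = 0.961); the text names them for these structures. Ureteric bud and collecting duct genes had 0 higher and 16 lower of 23 (1 and 16 adjusted over the list alone; median -2.02, or -2.01 with 10 members at their bound; camera adjusted p = 7.39e-08, or 0.0999 with an estimated correlation). Tmprss2, a membrane serine protease, was lower by at least 43.8-fold, adjusted p = 3.45e-07. Outside the list, Foxa1 was lower by at least 71.1-fold, adjusted p = 8.07e-07. Plet1, a surface protein of epithelial progenitors and also not a member, was lower by at least 63.6-fold, adjusted p = 5.58e-08. Gata3 did not pass (log2 change -0.77 ± 0.35, adjusted p = 0.104), and passed without renal vesicle replicate 3, which shares the fit (0.0406), with a pseudocount of 50 (0.0409) and on the 6 arrays of these groups alone (0.0401; 0.0401 to 0.339 over the alternatives). Wnt11 and Calb1 were each above background on 1 of 3 S-shaped body arrays and 0 of 3 collecting duct arrays (adjusted p = 0.0668 and 0.249). Wnt11 passed on the 6 arrays of these groups alone (0.0321), without renal vesicle replicate 3 (0.0229) or S-shaped body replicate 1 (0.0231), with array weights (0.0288), with a smaller pseudocount (0.0289) and on the deposited scale (0.0133), with 0.0133 to 0.253 over the alternatives.

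Junction and polarity genes had 1 higher and 21 lower of 23 (1 and 21 adjusted over the list alone; median -2.96, or -2.77 with 5 members at their bound; camera adjusted p = 6.26e-11, or 0.0743 with an estimated correlation). Cldn4 was lower by at least 39.2-fold, adjusted p = 5.58e-08, and Krt8 changed by -6.67 ± 0.85 (adjusted p = 0.000115). Endothelial genes were higher for 15 of 15 members (15 and 0 adjusted over the list alone), with a median of 4.53, or 3.44 with 12 members at their bound (camera adjusted p = 5.60e-12, or 0.0743 with an estimated correlation). Cldn5 was at least 52.3-fold, adjusted p = 1.12e-07. Gimap4, a GTPase of the immunity-associated family and not on that list, was at least 82.8-fold, adjusted p = 2.80e-08. Red blood cell genes had 5 higher and 0 lower of 9 (5 and 0 adjusted over the list alone; median 1.36, or 0.55 with 2 members at their bound; camera adjusted p = 0.00384, or 0.187 with an estimated correlation). Hbb-y, an embryonic globin, changed by 7.23 ± 0.93 (adjusted p = 0.000130; above background on 2 of 3 collecting duct arrays) and Hba-a1, an alpha globin, by 4.28 ± 0.69 (adjusted p = 0.000607). Hbb-b2, an adult beta globin that is not on the list, was at least 86.2-fold, adjusted p = 8.89e-07. Some globin genes have near-identical duplicates, from which their probe sets cannot be assumed to tell them. Stroma genes had 14 higher and 1 lower of 24 (14 and 1 adjusted over the list alone; median 1.36, or 0.75 with 13 members at their bound; camera adjusted p = 2.25e-06, or 0.179 with an estimated correlation). Cxcl12 was higher by at least 69.0-fold, adjusted p = 2.67e-07, and Acta2, smooth muscle actin, at least 14.6-fold, adjusted p = 1.36e-06. Basement membrane genes had 8 higher and 0 lower of 15 (8 and 0 adjusted over the list alone; median 0.73; camera adjusted p = 0.000511, or 0.123 with an estimated correlation). Nid2 was higher by at least 33.5-fold, adjusted p = 2.60e-08. Lama4 was at least 14.4-fold, adjusted p = 5.14e-08, but its other probe set was called in the opposite direction. Macrophage and leukocyte genes (2 higher and 1 lower of 6, camera adjusted p = 0.458) and neuron and glia genes (1 higher and 1 lower of 8, 0.843) were not called as lists.

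Immediate early and heat shock genes had 0 higher and 15 lower of 22 (0 and 16 adjusted over the list alone; median -1.73; camera adjusted p = 8.09e-06, or 0.123 with an estimated correlation). Atf3 was lower, at 5.93 ± 0.12 against 9.93 ± 0.46 (adjusted p = 9.39e-07), and Junb, a Jun family member, was lower by at least 5.32-fold, adjusted p = 0.000882. The collecting duct samples were unpooled and the S-shaped bodies pooled. Glycolysis genes had 1 higher and 7 lower of 14 (1 and 7 adjusted over the list alone; median -0.54; camera adjusted p = 0.00695, or 0.243 with an estimated correlation). Hk2, a hexokinase, was lower (log2 change -3.45 ± 0.34, adjusted p = 2.05e-05). Oxidative phosphorylation genes had 12 higher and 2 lower of 28 (13 and 2 adjusted over the list alone; median 0.45; camera adjusted p = 0.000627, or 0.259 with an estimated correlation). Cox7a2, a subunit of cytochrome oxidase, was higher (log2 change 2.88 ± 0.24, adjusted p = 6.12e-06). The lists of cell cycle (3 higher and 6 lower of 24, camera adjusted p = 0.757), Notch pathway (4 higher and 4 lower of 15, 0.970) and Wnt pathway genes (3 higher and 4 lower of 21, 0.607) were not called. Nor were those of proximal tubule (2 higher and 2 lower of 12, 0.790), distal tubule (2 higher and 2 lower of 9, 0.764) and ribosomal proteins (8 higher and 3 lower of 28, 0.236). limma called 3560 of 9316 probe sets between pooled S-shaped bodies and collecting duct, 1698 higher and 1862 lower in pooled S-shaped bodies, of which 2278 changed at least 2-fold. In 4867 probe sets (52.2%) the groups did not overlap, against 10% by chance.

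Pooled S-shaped bodies were compared with renal vesicles to follow the nephron from the earlier to the later stage. In S-shaped bodies 9 of 14 early nephron genes were lower and 1 higher, while 9 of 13 podocyte, 13 of 15 endothelial and 7 of 9 red blood cell genes were higher. With an estimated correlation these list calls were lost (adjusted p = 0.107, 0.343, 0.0999 and 0.158). Wnt4 averaged 7.62 ± 0.24 in renal vesicles and was under background in S-shaped bodies, lower by at least 7.76-fold, adjusted p = 2.29e-06. Pax8 fell from 8.32 ± 0.11 to 5.58 ± 0.58 (log2 change -2.74 ± 0.28, adjusted p = 4.10e-05), and Lhx1 fell as well (log2 change -1.66 ± 0.28, adjusted p = 0.00105). Wt1 did not pass the test (log2 change -0.63 ± 0.41, adjusted p = 0.263). Flt1, a receptor for vascular endothelial growth factor, averaged 8.27 ± 0.55 in S-shaped bodies and was under background in renal vesicles, at least 13.2-fold, adjusted p = 1.10e-05. Values are log2 signal ± SD for means and ± SE for changes, with 3 arrays in each group.

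Of 14 early nephron genes, 1 was higher, 9 lower and 4 did not pass (1 and 9 adjusted over the list alone), with a median log2 change of -1.50 (camera adjusted p = 0.00223, or 0.107 with an estimated correlation). Dll1 was lower by at least 6.44-fold, adjusted p = 2.29e-06. Nephron progenitor genes had 0 higher and 8 lower of 11 (0 and 9 adjusted over the list alone; median -1.33, or -1.003 with 4 members at their bound; camera adjusted p = 0.000588, or 0.107 with an estimated correlation). Uncx changed by -4.98 ± 0.34 (adjusted p = 5.27e-06; above background on 1 of 3 S-shaped body arrays), and Six2 fell from 7.96 ± 0.03 to 6.96 ± 0.36 (adjusted p = 0.00281). The series-named genes had 2 of 3 lower (median -2.74; camera adjusted p = 0.0105, or 0.123 with an estimated correlation); the text names them for these structures. Podocyte genes had 9 higher and 0 lower of 13 (9 and 0 adjusted over the list alone; median 1.18; camera adjusted p = 0.00148, or 0.343 with an estimated correlation). Synpo, an actin-associated protein of podocyte foot processes, changed by 3.16 ± 0.67 (adjusted p = 0.00357), and Tcf21, a podocyte transcription factor, by 2.67 ± 0.62 (adjusted p = 0.00584). Ureteric bud and collecting duct genes had 3 higher and 3 lower of 23 (3 and 3 adjusted over the list alone) and were not called as a list (camera adjusted p = 0.757). Gata3 rose (log2 change 2.51 ± 0.35, adjusted p = 0.000277), as did Krt7, a keratin (log2 change 4.24 ± 0.86, adjusted p = 0.00287; above background on 1 of 3 renal vesicle arrays). Wnt11 (log2 change -0.92 ± 0.69, adjusted p = 0.331) and Calb1 (log2 change 0.06 ± 1.42, adjusted p = 0.980) did not pass. Junction and polarity genes had 2 higher and 10 lower of 23 (2 and 11 adjusted over the list alone; median -0.66, or -0.63 with 3 members at their bound; camera adjusted p = 0.0235, or 0.343 with an estimated correlation). Epcam, an epithelial adhesion molecule, changed by -2.83 ± 0.47 (adjusted p = 0.000831, above background on 1 of 3 S-shaped body arrays). Without renal vesicle replicate 3 that list had a camera adjusted p of 0.0959, and 0.00146 to 0.0959 over the alternatives.

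Endothelial genes were higher in S-shaped bodies for 13 of 15 members (14 and 0 adjusted over the list alone), with a median of 3.47, or 3.39 with 2 members at their bound (camera adjusted p = 1.17e-08, or 0.0999 with an estimated correlation). Sox18, a transcription factor of vessel development, changed by 4.47 ± 0.38 (adjusted p = 1.56e-05, above background on 1 of 3 renal vesicle arrays). Outside the list, Fabp4, a fatty acid binding protein of capillaries and fat, changed by 4.97 ± 0.41 (adjusted p = 1.23e-05, above background on 2 of 3). Ednrb, an endothelin receptor and also not a member, was higher by at least 15.9-fold, adjusted p = 0.000119. The mean over the endothelial genes was 8.37 ± 0.21 in pooled and 8.23 ± 0.35 in single S-shaped bodies, 5.43 ± 0.52 in renal vesicles and 3.74 ± 0.05 in collecting duct (log2, SD, n = 3 each). Red blood cell genes had 7 higher and 0 lower of 9 (7 and 0 adjusted over the list alone; median 1.49, or 0.90 with 3 members at their bound; camera adjusted p = 0.00155, or 0.158 with an estimated correlation). Hba-a1 changed by 5.19 ± 0.69 (adjusted p = 0.000224) and Hbb-y by 5.26 ± 0.93 (adjusted p = 0.00132). Stroma genes had 8 higher and 3 lower of 24 (9 and 3 adjusted over the list alone; median 0.42; camera adjusted p = 0.0235, or 0.487 with an estimated correlation). Acta2 changed by 5.03 ± 0.39 (adjusted p = 8.41e-06, above background on 1 of 3 renal vesicle arrays) and Postn, periostin, by 3.48 ± 0.26 (adjusted p = 7.98e-06). The list was not called on the deposited scale or with a filter at the 50th percentile, with adjusted p of 0.00312 to 0.112 over the alternatives. Macrophage and leukocyte genes had 4 higher and 0 lower of 6 (4 and 0 adjusted over the list alone; median 1.20; camera adjusted p = 0.0238, or 0.243 with an estimated correlation). This call was lost on the deposited scale and with a filter at the 50th percentile (0.00952 to 0.274 over the alternatives). Ctss, a lysosomal protease, was higher by at least 4.37-fold, adjusted p = 3.13e-05. Basement membrane genes had 8 higher and 3 lower of 15 (10 and 3 adjusted over the list alone; median 0.73; camera adjusted p = 0.0425, or 0.295 with an estimated correlation). That call was lost without renal vesicle replicate 2 (0.0623) or 4 (0.0704), S-shaped body replicate 1 (0.0628) or 2 (0.0752), or collecting duct replicate 3 (0.0510), and its adjusted p was 0.0105 to 0.191 over the alternatives. Nid1, a nidogen, rose (log2 change 2.02 ± 0.33, adjusted p = 0.000836) and Lama1, a laminin chain, fell (log2 change -2.20 ± 0.49, adjusted p = 0.00504).

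Cell cycle genes were lower for 14 of 24 members and higher for 1 (16 and 1 adjusted over the list alone; median -0.90; camera adjusted p = 2.74e-05, or 0.127 with an estimated correlation). Mcm7, a subunit of the replicative helicase, fell (log2 change -2.17 ± 0.21, adjusted p = 2.94e-05), and Birc5, a mitotic regulator, was lower by at least 3.14-fold, adjusted p = 4.54e-05. Wnt pathway genes had 1 higher and 8 lower of 21 (2 and 8 adjusted over the list alone; median -0.70, or -0.37 with 8 members at their bound; camera adjusted p = 0.0276, or 0.127 with an estimated correlation). With a filter at the 50th percentile the list was not called (0.000411 to 0.0608 over the alternatives). Dkk1, a Wnt antagonist, was lower by at least 3.57-fold, adjusted p = 0.000210. Oxidative phosphorylation genes had 11 higher and 0 lower of 28 (12 and 0 adjusted over the list alone; median 0.33; camera adjusted p = 0.00351, or 0.328 with an estimated correlation). With scaling to the 75th percentile the list was not called (0.000480 to 0.0662 over the alternatives). Among the largest single differences, Slc32a1, a vesicular transporter of GABA, was lower by at least 8.48-fold, adjusted p = 6.22e-06, Ube2s, a ubiquitin-conjugating enzyme of mitosis, by at least 9.48-fold, adjusted p = 2.19e-06, and C1qtnf12 by at least 13.4-fold, adjusted p = 5.98e-06. The lists of immediate early and heat shock genes (5 higher and 7 lower of 22, camera adjusted p = 0.970), Notch pathway (2 higher and 4 lower of 15, 0.336) and glycolysis (2 higher and 5 lower of 14, 0.191) were not called. Nor were proximal tubule (0 higher and 2 lower of 12, 0.926), distal tubule (1 higher and 4 lower of 9, 0.209), neurons and glia (1 higher and 1 lower of 8, 0.989) and ribosomal proteins (5 higher and 1 lower of 28, 0.445). On the deposited scale the distal tubule and ribosomal lists were called (0.00819 and 0.0318; up to 0.435 and 0.694 over the alternatives). limma called 3423 of 9316 probe sets between pooled S-shaped bodies and renal vesicles, 1634 higher and 1789 lower in pooled S-shaped bodies, of which 2118 changed at least 2-fold. The groups did not overlap in 4419 probe sets (47.4%, with 10% by chance).

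**Figure D2:**
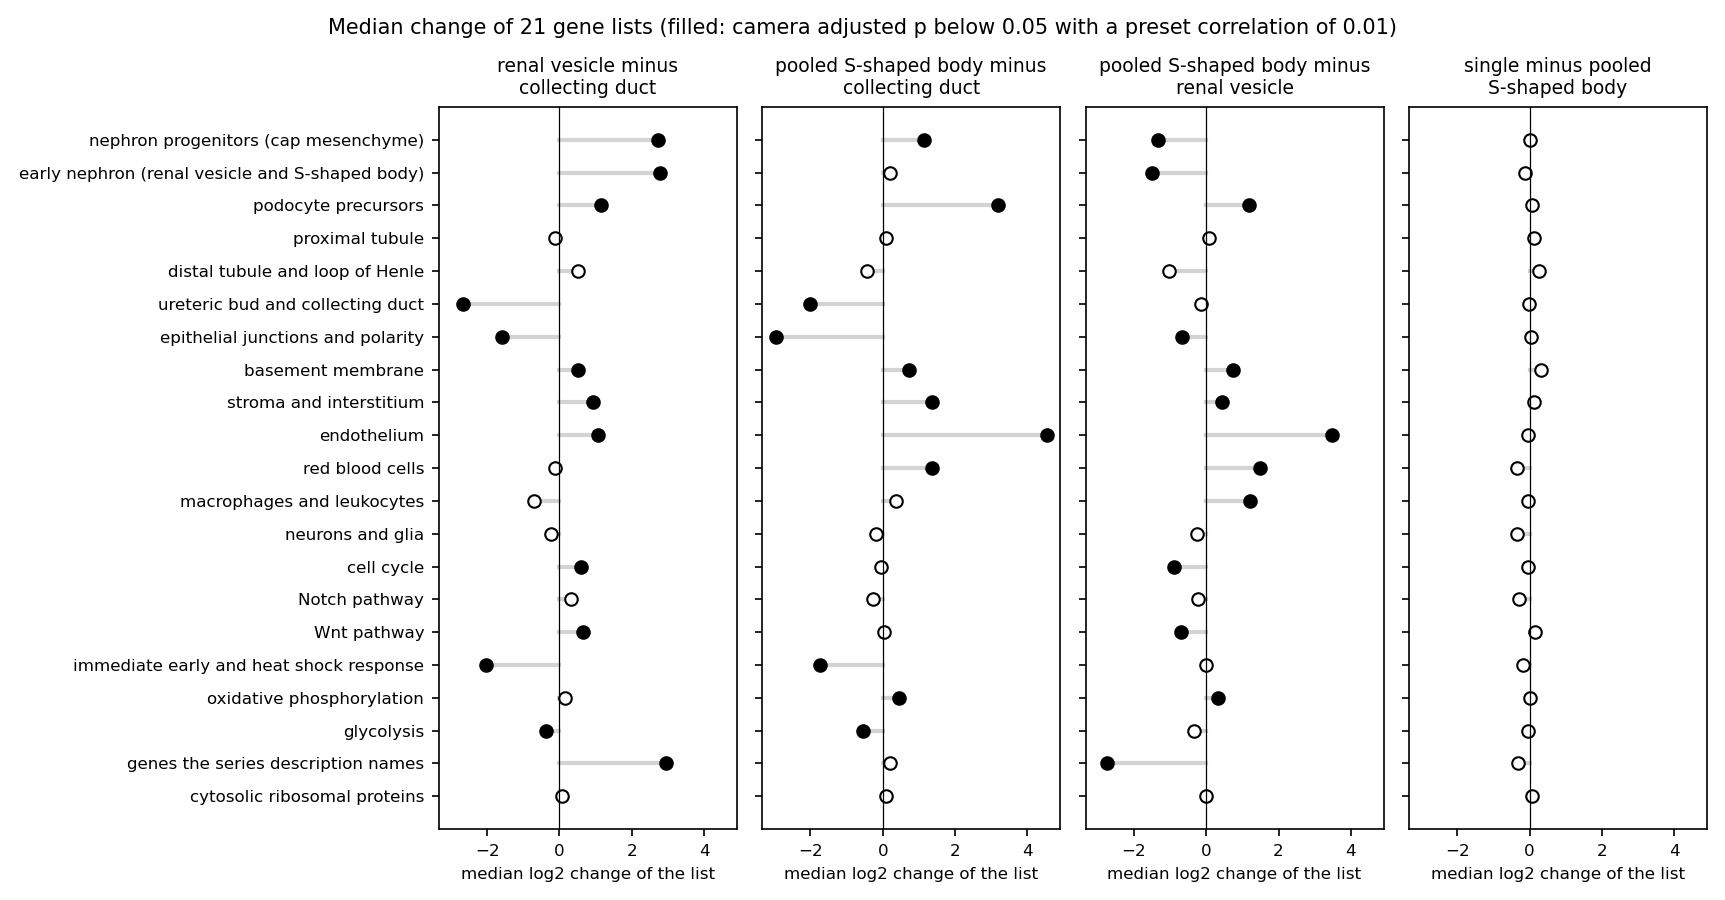
Median log2 change of the measured members of the 21 gene lists (horizontal axis) in 4 comparisons (panels); filled points have a camera adjusted p under 0.05 at the preset correlation, and 0 lists passed with an estimated correlation. The endothelium list lies at 4.53 for pooled S-shaped bodies against collecting duct and at -0.04 for single against pooled S-shaped bodies.

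Renal vesicles and S-shaped bodies share the collecting duct reference. Of the probe sets called in each comparison, 558 were higher in both structures and 585 lower in both, where independent lists of those sizes would share 209 and 216. The 3 collecting duct arrays are too few to divide between the comparisons, so part of the excess can come from the shared controls. The log2 changes correlated across probe sets with r = 0.59, against 0.50 in 20 simulations with no effect, and their covariance was 0.719 against 0.0801, a difference of 0.639. Another 165 probe sets were called in opposite directions, among them Wnt4, which was higher than collecting duct in renal vesicles and lower in S-shaped bodies. In the list tests of the 3 tissues, 37 of 63 were called at the preset correlation and 0 with an estimated correlation. Each called list had a median, a mean and a test of the same sign.

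Single S-shaped bodies were compared with pools of 20 to see what amplification from 1 structure changes. Few probe sets passed the test, and single arrays spread more than pools. Wt1 averaged 8.62 ± 0.30 in single and 8.17 ± 0.26 in pooled S-shaped bodies (log2 change 0.45 ± 0.22, adjusted p = 0.329). Six2 (-0.63 ± 0.43, adjusted p = 0.475), Pax8 (-1.08 ± 0.72, 0.475), Lhx1 (-0.13 ± 0.40, 0.901) and Gata3 (0.07 ± 0.42, 0.954) did not pass either. Pax8 and Lhx1 were each above background on 1 of 3 single arrays and on the 3 pooled arrays. Wnt11 and Calb1 were each above background on 1 of 3 pooled arrays and 0 of 3 single arrays (adjusted p = 0.589 and 0.299), and Wnt4 fell below the filter. Gdf3, a growth factor of the TGF-beta family, was higher in single structures (log2 change 4.33 ± 0.47, adjusted p = 0.0235; above background on 1 of 3 pooled arrays), as were Ddr2, a collagen receptor (at least 6.01-fold, adjusted p = 0.0251), and Serpind1, heparin cofactor II (at least 4.18-fold, adjusted p = 0.0235). Ldha, lactate dehydrogenase A, was lower (log2 change -1.42 ± 0.17, adjusted p = 0.0235), as was Gdnf, the ligand of Ret, by at least 2.56-fold, adjusted p = 0.0337. Another Gdnf probe set had the opposite sign and was not called. Each of these called genes lost its call without at least 1 array. Over the alternatives the adjusted p was 0.000133 to 0.112 for Gdf3, 0.000169 to 0.134 for Ddr2, 2.40e-05 to 0.141 for Serpind1, 0.00352 to 0.160 for Ldha and 0.000673 to 0.190 for Gdnf. The rule also selected Gpat4, Gon4l and Rps27l, called higher, and Eif3m, Saraf and Parl, called lower. Gon4l lost its call in 11 of 16 alternatives, Eif3m and Rps27l in 10 of 16 each and Parl in 9 of 16. Saraf lost it in 8 of 16 and Gpat4 in 6 of 15.

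limma called 37 of 9316 probe sets, 23 higher and 14 lower in single structures, and 1654 had an unadjusted p under 0.05. The count was 4, 1 and 3 without pooled replicates 1, 2 and 3, and 4, 12 and 72 without single replicates 3, 4 and 5. In a fit of all 12 arrays, which pools the spread of 4 groups, it was 424. In 2321 probe sets (24.9%) the single and pooled arrays did not overlap, where chance gives 10%. The low number of calls therefore does not show that single and pooled structures were alike. In simulated data with the spread of these arrays, the fit recovered 41.8%, 80.6% and 92.4% of probe sets changed by 1, 2 and 3 log2 units. Of the 20 lists with enough members, camera called 0 at the preset and 0 with an estimated correlation, with 1 and 0 at an unadjusted p under 0.05. The smallest adjusted p was that of basement membrane genes (0.0931; 0.0333 without pooled replicate 2; 0.00899 to 0.621 over the alternatives). Scaling to the 75th percentile called this list, ribosomal proteins (2.19e-07) and oxidative phosphorylation (0.0342). On the deposited scale ribosomal proteins (0.0131) and distal tubule genes (6.29e-06) were called. Over the alternatives the adjusted p of ribosomal proteins, oxidative phosphorylation and distal tubule genes reached 0.839, 0.860 and 0.695. The medians were -0.04 for endothelial, 0.08 for podocyte and -0.13 for early nephron genes. The median SD of a probe set was 0.40 in single structures against 0.21 in pools. Collecting duct, also unpooled, had 0.21, and pooled renal vesicles had 0.27. In single arrays the root mean square deviation from the group mean was higher by 0.30 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The share of probe sets above background differed by -5.00 percentage points (two-sided exact permutation p = 0.1).

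Single S-shaped bodies were set against collecting duct to ask how many genes 1 structure separates from the reference, next to the pools in a fit of the same size. In single structures, Cxcl12 (at least 101-fold, adjusted p = 5.18e-07), Foxc2 (at least 68.2-fold, adjusted p = 1.59e-06), Ptpro (at least 97.5-fold, adjusted p = 4.20e-06), Cdh5 (at least 50.6-fold, adjusted p = 1.12e-06) and Wt1 (log2 change 3.85 ± 0.26, adjusted p = 2.57e-05) were higher than in collecting duct. Krt19 (at least 77.2-fold, adjusted p = 5.18e-07), Cldn4 (at least 30.2-fold, adjusted p = 1.46e-05), Foxa1 (at least 54.7-fold, adjusted p = 3.34e-06) and Wnt4 (at least 2.13-fold, adjusted p = 0.000342) were lower. Six2 (log2 change 0.41 ± 0.42, adjusted p = 0.487) and Pax8 (log2 change -0.87 ± 0.69, adjusted p = 0.369) did not pass. Gata3 did not pass (log2 change -0.71 ± 0.37, adjusted p = 0.178), but passed without single replicate 5 (0.00832; 0.00832 to 0.425 over the alternatives). Lhx1 was above background on 1 of 3 single arrays and 0 of 3 collecting duct arrays (adjusted p = 0.00152). Podocyte genes had 11 higher and 1 lower of 13 (11 and 1 adjusted over the list alone; median 3.33; camera adjusted p = 1.40e-07, or 0.0760 with an estimated correlation). Endothelial genes had 14 higher and 0 lower of 15 (14 and 0 adjusted over the list alone; median 4.26, or 3.33 with 12 members at their bound; camera adjusted p = 1.49e-11, or 0.0760 with an estimated correlation). Ureteric bud and collecting duct genes had 0 higher and 16 lower of 21 (0 and 16 adjusted over the list alone; median -2.83; camera adjusted p = 2.63e-09, or 0.0520 with an estimated correlation). Junction genes had 1 higher and 20 lower of 23 (1 and 21 adjusted over the list alone; camera adjusted p = 9.45e-10, or 0.0937 with an estimated correlation). Immediate early and heat shock genes had 0 higher and 14 lower of 22 (1 and 16 adjusted over the list alone; median -1.87, or -1.74 with 3 members at their bound; camera adjusted p = 4.34e-06, or 0.102 with an estimated correlation).

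Stroma (11 higher and 0 lower of 25; camera adjusted p = 8.70e-06, or 0.0947 with an estimated correlation) and basement membrane genes (8 higher and 0 lower of 15; camera adjusted p = 0.000152, or 0.0760 with an estimated correlation) were called too. So were oxidative phosphorylation (10 higher and 1 lower of 28; camera adjusted p = 0.00306, or 0.363 with an estimated correlation) and glycolysis genes (0 higher and 7 lower of 15; camera adjusted p = 0.00283, or 0.264 with an estimated correlation). The call of oxidative phosphorylation was lost on the deposited scale (0.0603; 0.000215 to 0.0603 over the alternatives). Red blood cell genes had 4 higher and 0 lower of 9 (camera adjusted p = 0.0170, or 0.418 with an estimated correlation). Without single replicate 3 the adjusted p was 0.0933, and 0.00117 to 0.0933 over the alternatives. Ribosomal protein genes had 11 higher and 2 lower of 29 (camera adjusted p = 0.0497, or 0.464 with an estimated correlation). This call was lost without collecting duct replicate 1 (0.0516) or 3 (0.0839) and without single replicate 3 (0.109) or 4 (0.0565), with 0.000214 to 0.176 over the alternatives. Nephron progenitor genes, with 4 higher and 1 lower of 10, were not called (camera adjusted p = 0.111). They were called without collecting duct replicate 1 (0.0381) or 2 (0.0380) or single replicate 5 (0.0378), with 0.0378 to 0.304 over the alternatives. Early nephron genes (camera adjusted p = 0.400) were called on the deposited scale (0.00283) and with a filter at the 50th percentile (0.0455), with up to 0.480 over the alternatives. Distal tubule genes (camera adjusted p = 0.702) were called on the deposited scale (0.0194), with up to 0.891 over the alternatives. limma called 3152 of 9316 probe sets in single structures (1488 higher and 1664 lower) and 3826 in pools (1851 higher and 1975 lower), each with 6 arrays. The difference between these counts was not tested. Camera called 11 of 21 lists in single structures and 11 of 21 in pools, and 0 and 0 with an estimated correlation. Without 1 array at a time the count for single structures was between 2127 and 3308. Over the 9041 probe sets tested in both fits, 1140 were higher in both and 1303 lower in both, 280.0 and 363 being the overlap of independent lists, and 9 were called in opposite directions. Changes correlated across probe sets with r = 0.89 (0.51 simulated with no effect), with a covariance of 1.52 against 0.0797, and part of the excess over independent lists can come from the shared collecting duct arrays.

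**Figure D3:**
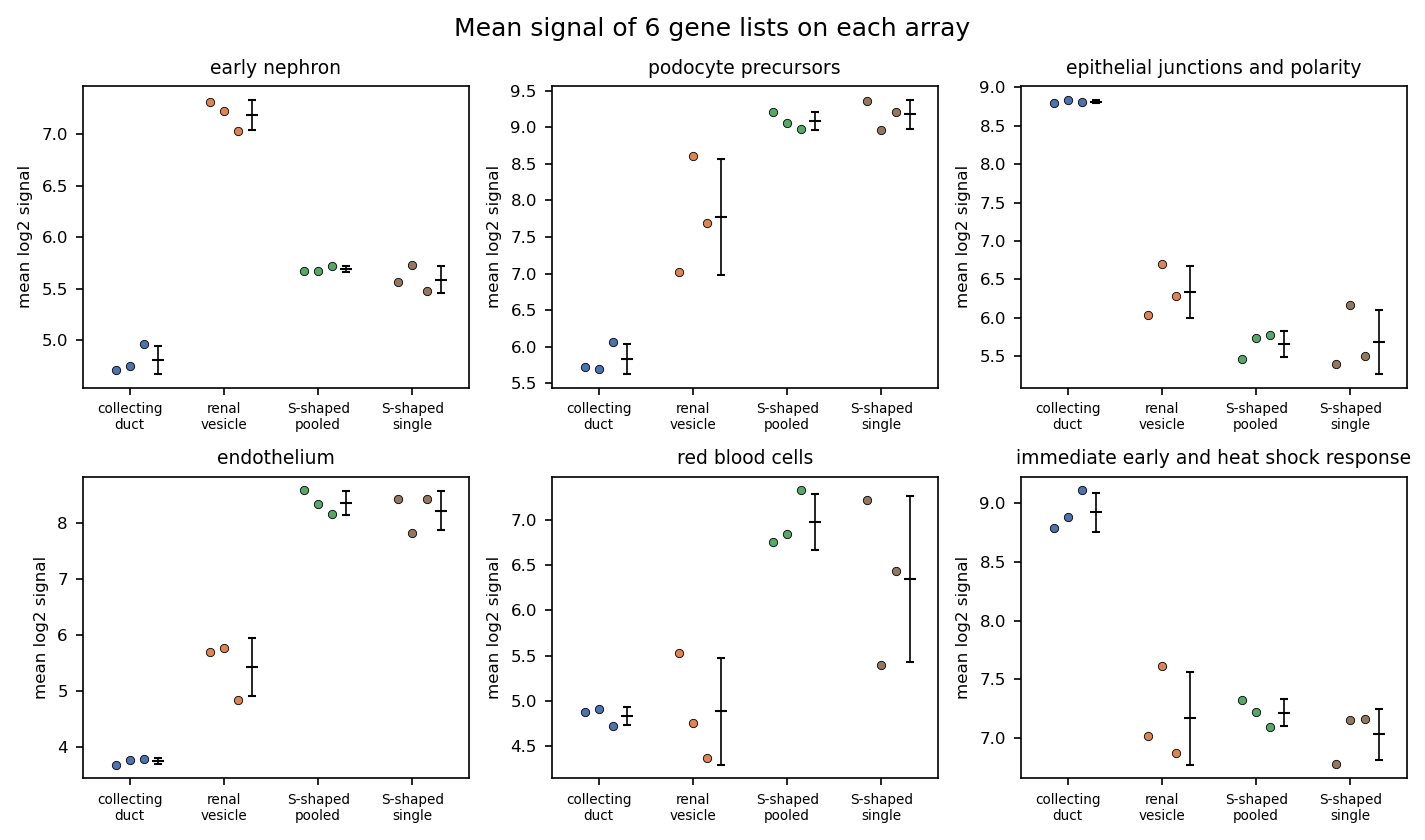
Mean log2 signal over the members of 6 gene lists (vertical axis) on the 12 arrays, by group; points are arrays and bars the mean ± SD of 3 arrays. The endothelium mean was 8.37 and 8.23 in pooled and single S-shaped bodies, against 5.43 in renal vesicles and 3.74 in collecting duct.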

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

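The tests of general carry-over, of dilution and of the handling of unpooled samples were chosen only after the result was seen. Renal vesicles and pooled S-shaped bodies differed from collecting duct in opposite directions for 165 probe sets, which stood out as a difference between the groups. Of the genes named in any comparison, 5 were higher than collecting duct in renal vesicles and lower in S-shaped bodies. Their differences, S-shaped body minus renal vesicle, were -4.91 for Ube2s, -4.77 for Wnt4, -3.18 for Dtx1, -2.84 for Dkk1 and -2.17 for Mcm7 on the log2 scale, with adjusted p between 2.19e-06 and 0.000210; Ube2s, Wnt4, Dtx1 and Dkk1 were under background in S-shaped bodies, so these fitted values are not bounds. Uqcrb, of the respiratory chain, and Sox18 went the other way, with differences of 2.50 (adjusted p = 7.45e-06) and 4.47 (adjusted p = 1.56e-05). Sox18 was above background on 1 of 3 renal vesicle arrays. The call of Uqcrb in renal vesicles against collecting duct was lost without renal vesicle replicate 2 (0.0659) or 3 (0.0736) and without collecting duct replicate 1 (0.108) or 2 (0.1005), with 0.0127 to 0.108 over the alternatives. Among the control probe sets, which no comparison used, the middle ribosomal RNA control of pooled S-shaped body replicate 1 read 3815, 4.03 times the highest collecting duct array, and the middle beta-actin control read 2712, 3.35 times the highest collecting duct array (deposited intensity).

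With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. Every split other than the real one mixes arrays of both groups, so a difference between the groups widens its spread and lowers its count. The gap between the counts therefore does not measure chance. In each of the 6 comparisons, 1 of 10 splits, the real split, called as many probe sets as were observed. The real split called 2225 for renal vesicles against collecting duct, where the highest other split called 0; 3560 against 0 for pooled S-shaped bodies and collecting duct; and 3423 against 1 for pooled S-shaped bodies and renal vesicles. On 6 arrays the counts were 37 against 1 for single and pooled S-shaped bodies, 3152 against 0 for single S-shaped bodies and collecting duct, and 3826 against 0 for pooled S-shaped bodies and collecting duct.

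Of 15 endothelial genes, 13 were higher in pooled S-shaped bodies than in renal vesicles, with a median log2 change of 3.47 (camera adjusted p = 1.17e-08, or 0.0999 with an estimated correlation); 15 were above background on every pooled S-shaped body array and 6 on every renal vesicle array, and 0 stand in another list. General carry-over of surrounding tissue would raise stroma alike, but the endothelial median exceeded the stroma median by 3.05 (95% bootstrap interval over genes 1.32 to 3.89). That interval measures the spread between genes, not between samples. By array, the endothelial mean was 4.82 to 5.77 in renal vesicles and 8.16 to 8.59 in pooled S-shaped bodies. The stroma mean was 5.15 to 5.87 and 6.23 to 6.47. These values argue against carry-over that raises both lists alike as the whole cause. Of 24 stroma genes, 16 were above background on every renal vesicle array and 19 on every pooled S-shaped body array. Members under background cannot show their full change, in either list. Stroma genes went both ways (8 higher and 3 lower of 24), and Acta2 (5.03), Postn (3.48) and 4 of 6 macrophage and leukocyte genes rose, so a part from carry-over stays open. Acta2 was above background on 1 of 3 renal vesicle arrays. A vessel caught in a few samples would leave some arrays low, but 6 of 6 S-shaped body arrays, pooled and single, lay above the highest renal vesicle array (lowest mean 7.83 against 5.77). What stays open, and was not tested, is whether vessel attached to or growing into each S-shaped body was dissected with it, which red blood cell genes could reflect too, or whether the cells of the structure itself differ between the stages.

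Of 14 early nephron genes, 9 were lower, 1 higher and 4 not called in pooled S-shaped bodies against renal vesicles, with a median log2 change of -1.50 (camera adjusted p = 0.00223, or 0.107 with an estimated correlation). Equal dilution by RNA of other cells would lower all members by about the same amount. The SD of their changes, 1.95, was 6.82 times the median standard error of a change, so the members did not fall alike. A wide spread was likely for any list, as 36.7% of all tested probe sets were called between these groups. Members under background, such as Wnt4 and Dll1, cannot show a full fall, and other cells may express some members. The test therefore cannot decide whether dilution contributed. An RNA length particular to the pools, which stood apart in the beta-actin 3′ to middle and Gapdh 3′ to 5′ ratios, would spare single S-shaped bodies, whose values of these ratios resembled those of renal vesicles. The median difference of single S-shaped bodies from renal vesicles was -1.72 (95% bootstrap interval over genes -3.22 to -0.47). Single arrays were also the dimmest (mean deposited intensity 47.0 against 116 in renal vesicles). Of the 14 genes, 5 were above background on every single array and 13 on every renal vesicle array. Low signal could give such a fall too, so this test cannot decide on RNA length. Not tested, and so open, are a separate effect of RNA length in single arrays, whose beta-actin 3′ to 5′ ratio was 85.7 ± 8.64 against 39.6 ± 3.61 (SD, n = 3 each), and a difference between the nephron stages; array batch or day of dissection, which the labels do not give, cannot be told apart from the group.

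Of 22 immediate early and heat shock genes, 15 were lower in pooled S-shaped bodies than in collecting duct and 7 were not called, with a median log2 change of -1.73 (camera adjusted p = 8.09e-06, or 0.123 with an estimated correlation). If the handling of unpooled samples were the cause, single S-shaped bodies would not differ from collecting duct. Their median change was -1.87 (95% bootstrap interval over genes -2.64 to -0.73). By array, the list mean was 6.78 to 7.16 in single S-shaped bodies and 8.78 to 9.11 in collecting duct. Single arrays were also the dimmest, with a mean deposited intensity of 47.0 against 304 in collecting duct. Of the 22 genes, 16 were above background on every single array and 21 on every collecting duct array. Being unpooled did not by itself go with high values of this list. Low signal could lower the values in single structures, however, so this test cannot decide on handling. The time from dissection to lysis and the order of dissection could differ between structures; the labels do not give them, and they cannot be told apart from the tissue. A difference between collecting duct and nephron cells in living tissue also stays open and was not tested.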

How the results depend on the processing

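The pseudocount of 50 was chosen after seeing the data, as were the floor at 0 and the background level; with it the calls were 2306, 3615, 3465, 34, 3178 and 3880 in the order of the comparisons in the text. Across all alternatives, 157 counts stayed within 1.5 times their value and 24 did not. Of the list results 2004 kept their side of the threshold, 99 lost a call and 22 gained it; of the values of named genes 4633 kept it, 168 lost it and 12 gained it. In none of these runs did a called value change sign. Among named genes, 15 values called in neither run did, and lists called in neither run were not counted for this. On the deposited scale the differences in brightness between arrays enter each comparison: the median of all log2 changes moved to -1.39 for renal vesicles against collecting duct, -0.46 for pooled S-shaped bodies against collecting duct, 0.94 against renal vesicles, -2.20 for single against pooled and -2.56 for single against collecting duct. Directions of genes and lists were taken relative to these shifts. The counts there were 7268 (3.23% higher, against 51.4% after quantile normalization), 3917 (24.7% against 47.7%), 5432 (93.9% against 47.7%), 8345 (0.252% against 62.2%) and 8299 (2.40% against 47.2%), and on 6 arrays 3950 for pooled S-shaped bodies against collecting duct (25.3% against 48.4%). Of these calls, 1647, 2808 and 2007 in the 3 comparisons of 9 arrays were also called after quantile normalization. The single and pooled arrays had 2 called lists on that scale.

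Single against pooled S-shaped bodies, with 37 calls (62.2% higher), gave 146 (78.1% higher) and 3 called lists with scaling to the 75th percentile. A filter at the 50th percentile gave 19 (73.7% higher, with 6211 probe sets tested). No filter gave 28 (50% higher, 8 of them shared with the 37), and leaving out the trend gave 39 (43.6% higher, 23 shared). The fit of all 12 arrays gave 424 (48.6% higher). There the smaller spread of the other groups enters and more arrays inform the spread, and these were not told apart. The cause of the other shifts was not tested. Asking for at least a 2-fold change as well left 1323 calls in renal vesicles against collecting duct, 2278 in pooled S-shaped bodies against collecting duct, 2118 against renal vesicles and 2336 on 6 arrays, by construction. With an estimated correlation, the 37, 11 and 11 list calls on 9 arrays, in single structures against collecting duct and in pools against collecting duct became 0, 0 and 0. Replicates with the same number did not deviate together (r -0.08 to 0.04 over 7 pairs, and -0.13 to 0.11 over 20 pairs with different numbers). No pairing by number was seen, though the labels do not say whether samples of the same number share an embryo or day. With the replicate number as a block the calls were 1383, 3346 and 2448 in the 3 comparisons of 9 arrays. Leaving out each array in turn gave 1640 to 2267 calls for renal vesicles against collecting duct, 2866 to 3719 for pooled S-shaped bodies against collecting duct, 2773 to 3401 against renal vesicles, 1 to 72 for single against pooled, 2127 to 3308 for single against collecting duct and 3225 to 3428 for pools against collecting duct on 6 arrays; the called lists ranged over 35 to 37 on 9 arrays, 0 to 1 for single against pooled, 9 to 12 for single against collecting duct and 10 to 11 for pools against collecting duct. Signal over background limits the dimmest arrays: 48.3% of probe sets were above background on the lowest single S-shaped body array.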

Other observations

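The 12 gene families tested here and the members named were all chosen only after the values were seen. Of 22 Hox genes, which pattern the body axis and the kidney, 9 were higher and 3 lower in renal vesicles than in collecting duct, and in pooled S-shaped bodies 8 were higher and 4 lower; the family median was above 0 in both comparisons under each of the 3 scalings. Hoxc9 was under background in collecting duct and higher by at least 4.24 log2 units in renal vesicles and 3.33 in S-shaped bodies (adjusted p = 2.78e-07 and 5.95e-07, n = 3 arrays each), and Hoxc6 by at least 2.86 and 3.96 (adjusted p = 2.36e-06 and 2.85e-07). Hoxa5 changed by 3.06 ± 0.18 and 2.89 ± 0.18 (adjusted p = 9.86e-07 and 8.26e-07). Hoxb7, expressed in the ureteric bud, was higher in collecting duct, with changes of -1.30 ± 0.17 and -1.52 ± 0.17 (adjusted p = 0.000298 and 5.12e-05), and so was Hoxd8, with -1.77 ± 0.19 and -2.00 ± 0.19 (adjusted p = 7.47e-05 and 1.75e-05). As a family they were not called (camera adjusted p = 0.105 in renal vesicles and 0.148 in S-shaped bodies, and 0.673 and 0.673 with an estimated correlation).

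Collagens had 10 higher and 1 lower of 24 in pooled S-shaped bodies against collecting duct (camera adjusted p = 0.0658). Col4a1 and Col4a2, the paired chains of basement membrane collagen, changed by 2.82 ± 0.10 and 2.83 ± 0.16 (adjusted p = 2.60e-08 and 3.45e-07), and by 2.28 ± 0.10 and 1.83 ± 0.16 in renal vesicles (adjusted p = 1.29e-07 and 1.26e-05). Keratins had 5 of 19 lower in renal vesicles than in collecting duct (camera adjusted p = 0.0658), among them Krt18, with -4.56 ± 0.23 (adjusted p = 3.00e-07). Igfbp3, a carrier of insulin-like growth factors, rose from 5.51 ± 1.27 in renal vesicles to 9.52 ± 0.29 in pooled S-shaped bodies (log2, SD, n = 3 each, adjusted p = 0.000139; above background on 2 of 3 renal vesicle arrays), and Nrp1, a receptor for semaphorins and vascular endothelial growth factor, changed by 2.69 ± 0.27 (adjusted p = 4.10e-05). Of 15 endothelial genes, 13 also rose between these groups. In 48 camera tests of the 12 families, 0 were called at the preset and 0 with an estimated correlation, with 9 and 1 at an unadjusted p under 0.05.

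Among genes with at least 2 called probe sets, the called signs disagreed for 8 of 133 (6.02%) in renal vesicles against collecting duct, 43 of 285 (15.1%) in pooled S-shaped bodies against collecting duct, 42 of 278 (15.1%) in pooled S-shaped bodies against renal vesicles and 42 of 230 (18.3%) in single S-shaped bodies against collecting duct.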
